A study of Apis mellifera with 3 samples.

How the data were processed

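The samples were antennae of honeybee workers (Apis mellifera) at 3 stages of adult life. Newly emerged workers were taken 1 to 2 h after leaving their cells, nurses were taken at 9 days of age while tending larvae, and foragers were taken at 21 days of age while returning with pollen. Antennae of 60 bees were pooled, and nuclei released by Dounce homogenisation entered a combined assay that reads RNA and open chromatin from the same nucleus (10x Genomics Multiome), per the labels. The labels speak of 3 replicates per stage and of 3 colonies. Analysed here was 1 library per stage, so stage, pool, colony mix and library preparation cannot be told apart in any comparison.

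Each library came as a matrix of deposited counts, made by the authors with Cell Ranger ARC 2.0.0 per the file headers. Its gene rows hold unique molecular identifiers (UMIs) per gene and nucleus, and its peak rows hold counts per open chromatin peak and nucleus. Cell Ranger and SAMtools are also listed in the submitters' processing notes, without versions. The genome build and the annotation were not given in the sources used here. The 12370 gene rows were identical in the 3 libraries and the peak rows differed, so peaks had been called per library. The matrices were used as deposited, with no normalization by the authors.

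Gene names and positions were those of the files. The NCBI RefSeq table of assembly Amel_HAv3.1, which holds 12174 of the 12370 gene identifiers, served for older names and for gene class. Its coordinates served for strand alone, which was set where only the start or only the end in the files matched them. Otherwise no strand was set. Only 853 genes carried a symbol that was not a bare locus number, so 11517 genes could be counted but not named. Positions are gene start sites, counted from 1.

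Nuclei were kept with at least 500 UMIs, at least 200 genes and at most 10% of UMIs from mitochondrially encoded genes. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 6%. It marked 3 of 11517 barcodes, 0.0261%, and so did not work on these libraries. The 6% of barcodes with the highest doublet scores of each library were therefore removed as an added alternative. The filter left 3490 nuclei of newly emerged workers, 3253 of nurses and 4539 of foragers.

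Nuclei of all libraries were clustered together without batch integration. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering (leidenalg 0.10.2) was run at resolution 1 on 15 neighbours. Named receptor genes (37 odorant, with Or2, and 2 gustatory) were kept out of the clustering. Genes without a name, which can include receptors, were not kept out. Clusters were named from marker lists alone. A cluster was olfactory sensory neuron-like where at least 3 of the 4 matched neuron markers (Syt1, Cac, brp and Para) and the co-receptor gene Or2 lay above the midpoint between the lowest and the highest cluster, and where no more support, epithelium or fat body markers than olfactory genes stood among its 10 leading genes by fold. A leading gene had to be present in 15% of the cluster's nuclei. Clusters with the neuron markers but without Or2 at that level were other neuron-like. Clusters with at least 3 support markers raised 3-fold or more, and at least 1 among the leading genes, were support cell-like. All others stayed unnamed. The midpoints, folds and minima of this naming rule were set after the clusters had been seen.

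UMIs were summed over nuclei per library and expressed as CPM (counts scaled to the same total in each library). Ratios were taken for nurse over newly emerged worker, forager over nurse and forager over newly emerged worker, over all nuclei and over olfactory sensory neuron-like nuclei. With 1 library per group no test was possible. Intervals are 95% exact Poisson (conditional binomial) intervals for ratios and 95% exact Clopper-Pearson intervals for shares, and they cover counting error only. A sum of 0 was set against a floor of 3 counts, and no ratio was taken where both sums were at or below it. For gene lists the median log2 ratio of members with at least 20 UMIs in the pair of libraries was taken, with an interval from 200 Poisson draws. Lists of at least 3 measured members were placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries.

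The lists were markers of neurons, olfactory and gustatory sensory neurons, glia, support cells, epithelium, muscle, hemocytes and fat body or oenocytes. They also covered odorant receptors, gustatory receptors, odorant-binding proteins, chemosensory proteins, the circadian clock, hormone response, cuticle formation, royal jelly proteins, immune effectors, ribosomal proteins, oxidative phosphorylation, heat shock proteins, biogenic amine receptors, detoxification and mitochondrially encoded genes. The lists of ionotropic receptors and their neurons, mechanosensory neurons, trachea and activity-induced genes matched 0 named genes and gave no result. The support list holds the 19 odorant-binding and 5 chemosensory proteins, and the epithelium list shares most members with cuticle formation. The detoxification list holds P450 and glutathione transferase genes, and not all act in detoxification, as with Cyp4g11 of hydrocarbon synthesis.

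Genes were named in the text by a fixed rule. For each comparison and each set of nuclei it took, among genes with a symbol and at least 100 UMIs, the 10 highest and the 10 lowest log2 ratios. It added up to 4 members of each list with the largest absolute ratio, and always Or2, Or11, Vg, Kr-h1, For, Per, Cry2 and Mrjp1. Ir25a, Ir8a, Ir76b, Hr38 and Egr were also to be named and were not matched. For co-expression it took the 6 neighbouring pairs with the highest mean Jaccard index.

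An odorant receptor gene was counted as present in a nucleus at 2 or more UMIs, Or2 left out. For shares of nuclei, each nucleus was thinned at random to 1000 UMIs and shallower nuclei were left out. Pairs of receptor genes present in at least 10 nuclei of a library were compared by the Jaccard index of their nuclei and by the number of shared nuclei over the number that independence predicts. Neighbours were pairs with start sites within 20 kb. A receptor gene had a peak where one lay within 500 bp of its start site, and its share was set against 10000 lists of protein-coding genes matched on expression. A run of receptor genes ended where the next named one started more than 50 kb away. Glia, epithelium and muscle classes, planned as background, could not be named, so support cell-like, other neuron-like and unnamed nuclei were used in their place.

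Comparisons, gene lists, the naming of genes, thresholds and other settings to be tried were fixed before the data were examined. These settings were doublets kept, a stricter nucleus filter and none, Leiden resolutions of 0.5 and 2, classes from Or2 UMIs, TMM scaling (edgeR 4.0.16) and size factors (DESeq2 1.42.0), nuclei weighted equally, equal class shares, other list minima, other UMI minima and depths, neighbours within 10 or 50 kb, and peaks within 200 or 1000 bp or in at least 1% of nuclei. Added after the data had been seen were the removal of nuclei with high doublet scores, totals without mitochondrially encoded genes, receptor counts that took in unnamed genes of the chromosome 2 run, 100 repeats of the random thinning, and 1000 resamples of nuclei for the intervals of pair ratios, since a nucleus counts for each pair it shares.

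The steps were checked on simulated data with known answers. For nurse over newly emerged worker over all nuclei, the interval held the simulated value for 96 of 100 genes set at 2-fold and 95 of 100 set at 4-fold, among 8509 genes. In the other comparisons and in the olfactory class this was 90 to 97 of 100, with the lowest value for forager over newly emerged worker over all nuclei. Simulated lists of unchanged genes fell between percentiles 1.34 and 95.19, so a percentile near either end was reached without a difference. With 30 simulated receptor genes in the newly emerged worker library, shared over expected nuclei came to 1.05 for neighbours made independent and to 16.8 for neighbours made to share nuclei.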

Results

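RNA and open chromatin were measured in nuclei of worker antennae at 3 stages of adult life, with 1 library of newly emerged workers, 1 of nurses and 1 of foragers. After filtering, the newly emerged worker library held 16848435 gene UMIs in 3490 nuclei, the nurse library 9019513 in 3253 nuclei and the forager library 21282784 in 4539 nuclei. Median depth was 4121 UMIs and 1578 genes per nucleus in newly emerged workers, 2242 UMIs and 1009 genes in nurses, and 2929 UMIs and 1268 genes in foragers. Median peak counts per nucleus were 5478.5, 5835 and 3113 in the same order, over 21401, 18487 and 14476 peaks. The median share of mitochondrially encoded UMIs was 1.31% in newly emerged workers, 0.0586% in nurses and 0.271% in foragers. No group had a replicate, so each difference below compares 3 libraries, and every interval covers counting error only.

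The libraries addressed how olfactory sensory neurons, the antennal cells that carry odorant receptors, differ between stages of work and how they use an expanded family of receptor genes. Olfactory sensory neuron-like nuclei were the largest class in every library. They made up 80.9% of nuclei in newly emerged workers (95% interval 79.5 to 82.2, 2823 nuclei), 72.6% in nurses (71.1 to 74.2, 2363 nuclei) and 55.8% in foragers (54.4 to 57.3, 2534 nuclei). Other neuron-like nuclei, with neuron markers but less Or2 RNA, were 3.04%, 1.91% and 5.64% in the same order. They were cluster 7 alone, at median depths of 8311, 5613.5 and 7416.5 UMIs, against 4019, 2220 and 2623.5 in the olfactory class. Multiplets in cluster 7 were not tested and are not excluded. Support cell-like nuclei, led by the odorant-binding protein genes Obp7, Obp6 and Obp2, were 1.49%, 3.38% and 2.42%. These shares depend on the naming rule. Unnamed clusters 11, 5 and 18 had 9, 8 and 6 support markers raised, against 5 in support cell-like clusters 13 and 24. Cluster 18 held 128 nuclei, all of newly emerged workers. Unnamed nuclei were 14.6%, 22.1% and 36.1%, and cluster 17, kept out of the olfactory class by a naming rule set after the clusters were seen, held 41, 9 and 93 nuclei. The olfactory class was split by library. Clusters 1, 3 and 16 held nearly all of it in newly emerged workers, with 1445, 1208 and 165 nuclei, whereas clusters 0, 2, 4, 6 and 8 held it in nurses and foragers. Clusters 1 and 3 held 1 nurse nucleus each and 0 forager nuclei, and a cluster from nearly 1 library alone can be that library and not a type of neuron. Support cell-like nuclei were split in the same way, with cluster 24 in newly emerged workers and cluster 13 in nurses and foragers.

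**Figure D1:**
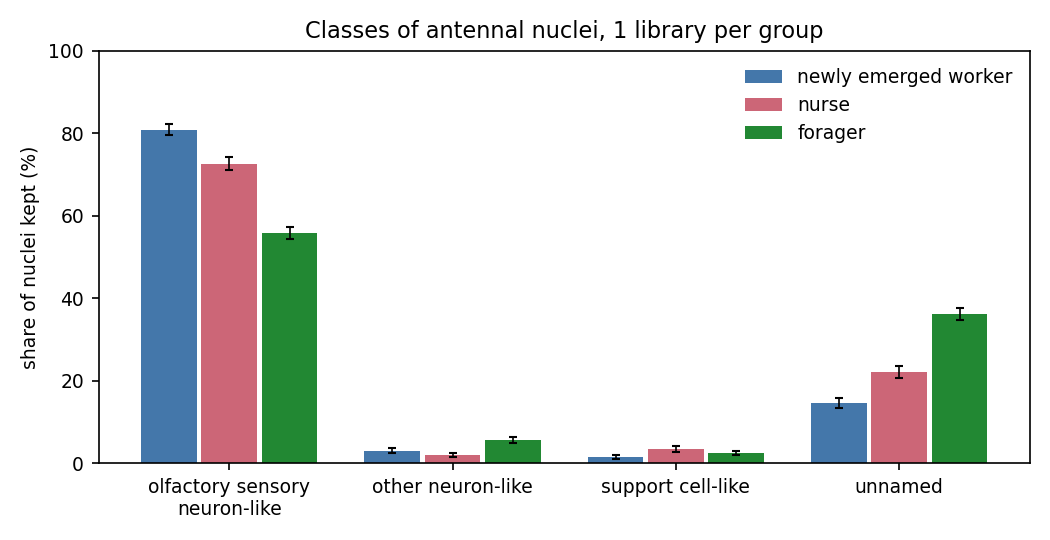
Share of kept nuclei in each class (percent, vertical axis) for the newly emerged worker, nurse and forager libraries, 1 library each, with bars for shares and error bars for 95% exact Clopper-Pearson intervals. The olfactory sensory neuron-like share was 80.9%, 72.6% and 55.8%, and the unnamed share 14.6%, 22.1% and 36.1%.

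Or2, the co-receptor that odorant receptors need, lies on chromosome 1 with its start at 5723757. In olfactory sensory neuron-like nuclei it stood at 1185, 1067 and 1147 CPM (counts scaled to the library total, here that of the class) in newly emerged workers, nurses and foragers, and 94.5%, 81.4% and 84.8% of these nuclei held a UMI at median depths of 4019, 2220 and 2623.5 UMIs. In unnamed nuclei it stood at 311, 348 and 513 CPM, with a UMI in 30.5%, 30.2% and 53.8% of nuclei at median depths of 4426, 2278 and 3760. Or2 was part of the naming rule, as clusters entered the olfactory class only with Or2 above the midpoint. Its high level there and its contrast with unnamed nuclei follow in part from that rule. The rule also limits how far Or2 can differ between libraries within the class. The ratio of Or2 between libraries there was small and had no settled direction. Nurse over newly emerged worker was -0.15 on the log2 scale (-0.19 to -0.11), but 0.01 under TMM scaling and 0.08 under DESeq2 size factors. Forager over nurse was 0.10 (0.06 to 0.15), but -0.07 and -0.11 under those scalings. Forager over newly emerged worker was -0.05 (-0.08 to -0.01).

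The first comparison set nurses against newly emerged workers and asked what separates the antenna of a bee at nursing work from that of a bee that has just left its cell. The nurse library held far less RNA for energy metabolism and less for ribosomal, chemosensory and cuticle proteins, and more RNA of a serotonin receptor, some odorant-binding proteins and a juvenile hormone-induced transcription factor. The serotonin receptor gene 5-HT1, on chromosome 13 at 4679854, was 10.9-fold higher in the nurse library, a log2 ratio of 3.45 (3.17 to 3.74) from 701 against 120 UMIs. Kr-h1, the juvenile hormone-induced factor on chromosome 6 at 16507519, was 3.47-fold higher, with a log2 ratio of 1.79 (1.69 to 1.90). Apd-2, an apidermin of the cuticle on chromosome 4 at 4489933, had 2 UMIs in the nurse library against 1153, a log2 ratio of -8.27 (-11.32 to -6.41). Across 8392 genes with at least 100 UMIs, the median absolute log2 ratio was 0.49.

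All 13 mitochondrially encoded genes were lower in the nurse library by 2-fold or more, with a median log2 ratio of -4.66 (-4.83 to -4.38), below all 10000 matched random lists. The genes mt-ND6, mt-ND4, mt-COX3 and mt-ATP6 had log2 ratios of -6.33, -5.39, -5.05 and -4.82. The 7 nuclear genes of oxidative phosphorylation were also each lower by 2-fold or more, with a median of -2.53 (-2.75 to -2.33), below all random lists. Among them Cox6c stood at -4.36, Ndufs5 at -3.51 and Uqcr11 at -3.20. Ribosomal protein genes had a median of -1.28 (-1.38 to -1.19), at percentile 0.05 of random lists, with 5 of 7 lower by 2-fold or more, among them RpLP1 at -1.28 and Rpl41 at -1.58. The mitochondrial share of UMIs, a sign of carried-over cytoplasm in preparations of nuclei, moved with these groups.

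Chemosensory proteins, small secreted carrier proteins, were lower in the nurse library by 2-fold or more in 5 of 5 genes, with a median of -2.18 (-2.36 to -2.03) at percentile 0.02. CSP3 was 5.43-fold lower and CSP1 4.62-fold lower. Cuticle formation genes had a median of -1.45 (-1.86 to -1.04), at percentile 0.02, with 9 of 15 measured genes lower by 2-fold or more and 1 higher. The cuticular protein gene CPR14 was 8.97-fold lower. The overlapping epithelium markers had a median of -1.32, at percentile 0.09. Apd-2 was also a leading gene of cluster 25, which held 28 nuclei, all of newly emerged workers. Immune effectors had a median of -2.49 over 3 measured genes, and the phenoloxidase precursor gene PPO, the only hemocyte marker matched, had 2 UMIs against 21.

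Odorant-binding proteins, which carry odorants in the fluid around sensory dendrites, had a median of 0.26 (0.09 to 0.53), at percentile 96.6. Of 15 measured genes 5 were higher by 2-fold or more and 1 was lower, and Obp21 and Obp19 were 5.68-fold and 4.31-fold higher. The support cell list that holds them had a median of -0.06 (-0.16 to 0.04), with no settled direction. Biogenic amine receptors had a median of -0.27 (-0.65 to -0.16), at percentile 34.8, with 5-HT1 at 3.45 and the serotonin receptor 5-HT2beta at -1.62. Hormone response genes had a median of 0.33 (0.26 to 0.37), where the ecdysone-induced receptor E75 stood at 0.82 and the juvenile hormone esterase Jhe at -1.90. The detoxification list had a median of 0.01 (-0.36 to 0.36), with the cytochrome P450 gene CYP6AS11 at 1.56 and the glutathione transferase gene GstD1 at -1.79. Within the olfactory class that list had a median of 0.60 (0.20 to 0.82) over 6 measured genes, 4 higher and 2 lower. Heat shock proteins had a median of -0.38 (-0.50 to -0.27), at percentile 9.54, and Hsc70-4 stood at -1.27. Of the clock genes Per was 2.07-fold higher in the nurse library and Cry2 1.68-fold lower. The DNA methyltransferase gene Dnmt1a was 2.95-fold higher, and For, a cGMP-dependent protein kinase, stood at 0.58 (0.49 to 0.67).

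The 36 odorant receptor genes had a median log2 ratio of -0.50 (-0.63 to -0.42) for nurse over newly emerged worker, at percentile 22.2 of matched lists, with 32 lower and 4 higher. Of these 6 were lower by 2-fold or more, among them Or12 at -1.24, and Or11, the receptor for the main queen pheromone component, stood at -0.95 (-1.39 to -0.52). Neuron markers had a median of -0.01 (-0.03 to 0.00), with brp at 0.18, Para at 0.15, Syt1 at -0.42 and Cac at -0.18, which became 0.18 with equal class shares. The glia marker Eaat-2 stood at -0.60, the muscle genes TpnI and TpnT at 2.00 and 0.43, the fat body list at -0.26 from 1 measured gene, the gustatory list at -2.04 from 3 against 23 UMIs of Gr10-b, and the royal jelly list at -1.68 from 5 against 30 UMIs of Mrjp9, which became 0.79 with equal class shares. Eaat-2, the only glia marker matched, was highest in olfactory sensory neuron-like clusters 16, 3 and 1, at 117, 113 and 101 CPM. No glia class was named, so its ratios in the 3 comparisons are not a reading of glia. Vg had 0 UMIs in nurses and 4 in newly emerged workers, and Mrjp1 had 1 and 0, so neither could be compared. TMM scaling raised all nurse values by 0.14 on the log2 scale and DESeq2 size factors by 0.18, and all ratios are given on CPM.

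Within olfactory sensory neuron-like nuclei, with newly emerged workers in clusters 1, 3 and 16 and nurses mainly in clusters 2, 4 and 6, the same lists stood apart. Mitochondrially encoded genes had a median of -4.87, oxidative phosphorylation genes of -2.61 (-2.95 to -2.40) with 7 of 7 lower by 2-fold or more, and ribosomal protein genes of -1.01 (-1.16 to -0.91). 5-HT1 was 14.5-fold higher in the nurse library, a log2 ratio of 3.86 (3.52 to 4.21), and it was among the leading genes of clusters 0 and 2. Dnmt1a stood at 1.86 (1.54 to 2.18), Kr-h1 at 1.72 (1.59 to 1.84), 5-HT2beta at -1.58 and Hsc70-4 at -1.08. Odorant receptors had a median of -0.52 (-0.65 to -0.41) over 35 measured genes, at percentile 26.6, with 6 lower by 2-fold or more, among them Or170 at -1.31 and Or107 at -1.57. In 248 newly emerged worker nuclei no deeper than the nurse median, a set chosen after the result was seen, the receptor median of newly emerged worker over nurse was -0.38 with an interval that includes 0 (-0.50 to 0.09), against 0.55 (0.41 to 0.65) in all nuclei of the class.

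**Figure D2:**
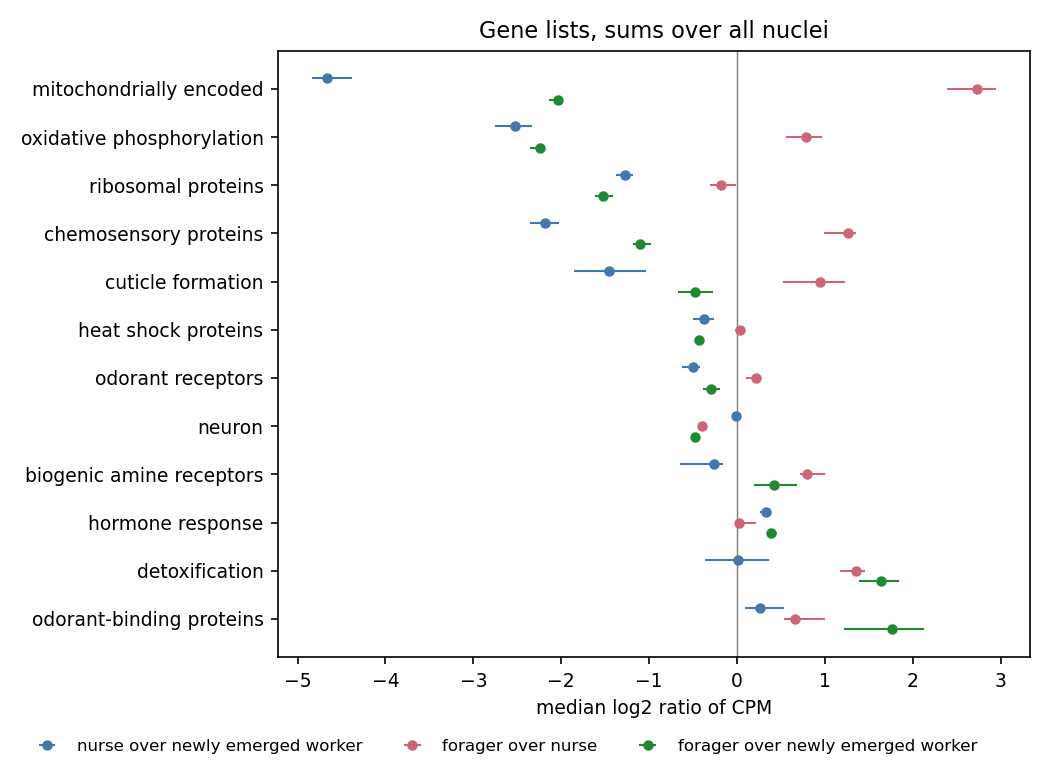
Median log2 ratio of CPM (horizontal axis) of the genes in 12 lists, summed over all nuclei, for the 3 comparisons, with points for medians and lines for 95% intervals of counting error. Mitochondrially encoded genes reach -4.66 for nurse over newly emerged worker and 2.73 for forager over nurse. For forager over nurse the odorant receptor median turns negative under DESeq2 size factors, the biogenic amine receptor median under equal class shares and the hormone response median under both and under TMM scaling, and for forager over newly emerged worker the odorant receptor, neuron and detoxification medians change sign under equal class shares.

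The comparison of foragers with nurses asked what separates the antenna of a bee that collects pollen from that of a bee that tends brood. The forager library held more RNA of the detoxification list, odorant-binding proteins, chemosensory proteins and cuticle genes, and less RNA of neuron markers. Sums over all nuclei weigh each nucleus by its UMIs. The olfactory class held 74.5%, 66.3% and 36.8% of UMIs in newly emerged workers, nurses and foragers, and unnamed nuclei 17.4%, 24.2% and 49.9%. Ratios over all nuclei can therefore also follow these shares. TyHyd, the tyrosine hydroxylase of cuticle hardening and dopamine synthesis, was 6.22-fold higher in foragers (log2 2.64, 2.35 to 2.94). Obp16, Obp19 and Obp15, neighbours on chromosome 15 at 1934983, 1948873 and 1932182, were 3.97-fold, 3.94-fold and 3.95-fold higher. The olfactory class was smaller in foragers by clusters, at 55.8% against 72.6% of nuclei, but nuclei with 1 or more Or2 UMIs were 72.2% against 68.1%. The median absolute log2 ratio was 0.26 over 8673 genes.

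Detoxification genes had a median log2 ratio of 1.36 (1.17 to 1.46) for forager over nurse, at percentile 100 of matched lists, with 5 of 7 measured genes higher by 2-fold or more and 0 lower. Cyp4g11, a P450 of hydrocarbon synthesis, had 116 UMIs against 7, GstS1 was 4.02-fold higher and CYP6AS11 2.57-fold higher. Odorant-binding proteins had a median of 0.65 (0.54 to 1.00), with 7 of 17 higher by 2-fold or more and 0 lower, and the support list stood at 1.00 (0.77 to 1.08). Chemosensory proteins had a median of 1.27 (0.99 to 1.36), with CSP1 at 1.86, CSP3 at 1.27 and CSP4 at 1.07. Cuticle formation genes stood at 0.95 (0.53 to 1.23) with all 15 higher, among them Y-y of the yellow family at 2.27, and epithelium markers stood at 0.89 (0.43 to 1.02). Immune effectors had a median of 2.62 (1.76 to 3.49) over 4 genes, with the defensin gene Def1 at 124 against 4 UMIs and PPO at 68 against 2, a log2 ratio of 3.85 (1.94 to 6.92). Both royal jelly genes measured were higher, with a median of 3.40 (2.67 to 4.51) and Mrjp9 at 173 against 5 UMIs. The glucosidase gene Hbg3 was 8.40-fold higher.

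Biogenic amine receptors had a median of 0.79 (0.71 to 1.00) for forager over nurse, with the tyramine receptor TyrR at 1.27 and the dopamine receptor DopR2 at 1.22. With equal class shares in each library this median was -0.02. Clock genes had a median of 0.82 (0.73 to 0.92), with Per at 0.68 and Cry2 at 0.97, but of 0.16 within the olfactory class, with 1 gene higher and 1 lower. Neuron markers were lower in foragers, with a median of -0.40 (-0.41 to -0.39) at percentile 0.47, where brp, a scaffold of presynaptic release sites, stood at -0.70, the sodium channel Para at -0.46 and the calcium channel Cac at -0.34. Heat shock proteins and hormone response genes had medians of 0.03 and 0.02, both with a negative sign under TMM scaling and DESeq2 size factors, and Kr-h1 stood at 0.25 (0.18 to 0.32). For was at 0.02 (-0.06 to 0.09), a difference not detectable at this depth. The muscle genes TpnI and TpnT stood at -0.93 and -1.24, and Eaat-2 at -0.43. The fat body list stood at 0.01 from 1 measured gene, and no gustatory gene had enough UMIs.

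Mitochondrially encoded genes had a median of 2.73 (2.39 to 2.94) for forager over nurse, at percentile 100, with 12 of 13 higher by 2-fold or more, among them mt-ND6 at 3.74 and mt-ND4 at 3.24. Oxidative phosphorylation genes had a median of 0.78 (0.56 to 0.97), with Cox6c at 2.12, and ribosomal protein genes stood at -0.19 (-0.31 to -0.02). The 36 odorant receptors had a median of 0.22 (0.10 to 0.29) over all nuclei, at percentile 20.2, and of -0.01 under DESeq2 size factors. Or2 stood at -0.16 (-0.20 to -0.12) over all nuclei, but at 0.16 with equal class shares. Or151 was higher in foragers, at 0.80 (0.65 to 0.94), but not in unnamed cluster 20, which was picked out afterwards. There it stood at 2249.5 CPM in nurses and 1942.9 in foragers. Outside that cluster and the olfactory class it stood at 66.3 CPM in nurses and 113 in foragers.

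Within olfactory sensory neuron-like nuclei, where foragers lay mainly in cluster 0 and nurses mainly in cluster 2, the median absolute log2 ratio for forager over nurse was 0.22 over 6812 genes. Odorant receptors had a median of 0.34 (0.24 to 0.45) over 35 genes, at percentile 91.8, with Or151 at 1.53, Or107 at 1.61 from 36 against 9 UMIs, Or19 at 0.93 and Or11 at 0.56 (0.03 to 1.11). Or151 stood at 9.87 and 28.6 CPM in the class in nurses and foragers, but at 137 and 128 outside it. Odorant-binding proteins stood at 0.99 (0.72 to 1.16) in the class, with Obp19 at 2.18 and Obp16 at 1.77, and detoxification genes at 1.14 (0.78 to 1.48). Support, epithelium and cuticle lists, at 0.87, 0.75 and 0.91, and mitochondrially encoded genes, at 2.06 with 12 of 12 higher, moved with them, so RNA of other cells in these nuclei is not excluded. The neuron markers stood at -0.23 (-0.24 to -0.21), with brp at -0.51. Ribosomal protein genes had a median of -0.55 (-0.73 to -0.36), with RpLP1 at -0.63, and heat shock proteins of -0.26, with Hsc70-4 at -0.40. Kr-h1 stood at 0.21 (0.11 to 0.31).

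The comparison of foragers with newly emerged workers spanned the whole age range. The forager library held more RNA of odorant-binding proteins and the detoxification list, and less RNA for energy metabolism and ribosomes. Obp19 and Obp21, on chromosome 15 at 1948873 and 1959554, were 17.0-fold and 11.9-fold higher in foragers. 5-HT1 was 13.4-fold higher within the olfactory class, and Kr-h1 was 4.12-fold higher over all nuclei. Glurb, a metabotropic glutamate receptor and the leading gene of cluster 1, was 5.34-fold lower in foragers, and Apd-2 had 12 UMIs against 1153. The median absolute log2 ratio was 0.45 over 9027 genes.

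Odorant-binding proteins had a median of 1.76 (1.21 to 2.13) for forager over newly emerged worker, at percentile 100, with 9 of 17 higher by 2-fold or more and 1 lower, and Obp12 at 3.27. The support list stood at 0.64 (0.53 to 0.90). Detoxification genes had a median of 1.64 (1.38 to 1.84), with CYP6AS11 at 2.92 and Cyp4g11 at 2.82, but of -0.22 with equal class shares. Within the olfactory class the detoxification median was 1.93 (1.57 to 2.36) over 7 measured genes, 6 higher and 1 lower. Per was 3.33-fold higher, with a clock median of 0.98 (0.91 to 1.05), while within the olfactory class Per and Cry2 had a median of -0.02 and Cry2 stood at -1.01. For stood at 0.59 (0.52 to 0.67), but at -0.59 with equal class shares, and at 1.37 (1.02 to 1.73) within the olfactory class. The corazonin receptor gene Crzr was 14.7-fold higher, and it was among the leading genes of cluster 5, which held 401 forager nuclei. TpnCIIIb, a troponin C, had 109 UMIs against 2, a log2 ratio of 5.43 (3.54 to 8.49). The glucosidase genes Hbg3 and AGLU2 stood at 4.80 and 3.10, and Dat at 2.96. Within the olfactory class the transferrin gene Tsf1 stood at 2.93.

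Mitochondrially encoded genes had a median of -2.04 (-2.14 to -1.99) for forager over newly emerged worker, oxidative phosphorylation genes of -2.24 (-2.35 to -2.20) and ribosomal protein genes of -1.52 (-1.61 to -1.41), and for each list this median lay at percentile 0. The genes mt-ND6 and Ndufs5 stood at -2.59 and -2.42 over all nuclei, RpLP1 at -1.59, and Ndufb2 at -3.04 within the olfactory class. Chemosensory proteins had a median of -1.11 (-1.18 to -0.98), with CSP3 at -1.17. Cuticle formation and epithelium lists stood at -0.48 (-0.67 to -0.28) and -0.52 (-0.80 to -0.35), with Y-h of the yellow family at 50 against 2 UMIs. The fatty acid-binding protein gene Fabp stood at -2.39, and Eaat-2 at -1.03. Hormone response genes stood at 0.38, heat shock proteins at -0.43, immune effectors at 0.54 with 2 genes higher and 2 lower, biogenic amine receptors at 0.42 with the dopamine receptor Dop1 at 1.33, muscle genes at 0.13, the fat body list at 0.75, the hemocyte gene PPO at 1.36, the gustatory list at -1.28 and royal jelly genes at 2.77 with Mrjp8 at 3.35. Within the olfactory class immune effectors stood at -2.40 from 2 measured genes and biogenic amine receptors at -0.27 (-0.44 to 0.37).

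Odorant receptors had a median of -0.30 (-0.38 to -0.20) for forager over newly emerged worker over all nuclei, and Or2 stood at -0.36 (-0.39 to -0.33). With equal class shares these became 0.30 and 0.41, and the neuron marker median of -0.47 became 0.13. Within the olfactory class the receptor median was -0.15 (-0.28 to -0.02), at percentile 49.2, with 15 higher and 21 lower. Or170, on chromosome 7 at 8690955, was 3.24-fold lower in the forager class, and Or12 was 2.03-fold lower over all nuclei.

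The number of odorant receptor genes per nucleus was counted because a sensory neuron is usually described by the receptor it uses. At 1000 UMIs per nucleus, 9.49% of olfactory sensory neuron-like nuclei of newly emerged workers held 1 or more named receptor genes at 2 or more UMIs (8.43 to 10.6, 266 of 2802 nuclei). In nurses it was 5.21% (4.33 to 6.21) and in foragers 6.80% (5.84 to 7.87). 2 or more receptor genes were found in 0.892%, 0.663% and 0.733% of nuclei. These were 9.40% (6.17 to 13.6), 12.7% (7.29 to 20.1) and 10.8% (6.51 to 16.5) of the nuclei with a receptor. The random draw of UMIs moved these shares. For 2 or more receptors the means over 100 draws were 0.877%, 0.507% and 0.513%, so the draw printed was high in nurses and foragers. Over 100 draws the share with 1 or more receptors was 8.67% or more in newly emerged workers, with a mean of 9.70%, and ran from 4.73% to 6.36% in nurses, with a mean of 5.45%, and from 5.30% to 6.97% in foragers, with a mean of 6.22%. The ranges of nurses and foragers overlapped, so their order rests on a small difference. Thinning left out 21, 100 and 79 nuclei as too shallow. At full depth the shares with 1 or more receptors were 33.5%, 16.3% and 22.1%, and with 2 or more 12.9%, 4.02% and 6.47%.

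In support cell-like nuclei, a background that itself held Or2 at 55.0, 414 and 422 CPM in newly emerged workers, nurses and foragers, the thinned share with 1 or more receptors was 0 of 52 nuclei in newly emerged workers, which allows up to 6.85%, and 0.990% and 0.943% in nurses and foragers, at median depths of 3671, 1929.5 and 2418.5 UMIs. In unnamed nuclei it was 7.74%, 4.85% and 4.34%, and in other neuron-like nuclei 4.72%, 1.61% and 2.34%. The intervals of unnamed nuclei, 5.56 to 10.4 in newly emerged workers and 3.29 to 6.85 in nurses, overlapped those of the olfactory class. In foragers the olfactory class, at 5.84 to 7.87, lay above unnamed (3.37 to 5.49), other neuron-like (0.865 to 5.03) and support cell-like nuclei (0.0239 to 5.14), and over 100 draws it was at least 5.30% against at most 5.13% in unnamed nuclei, but with called doublets kept its interval was 4.88 to 6.70. At full depth the shares in unnamed nuclei were 23.6%, 13.5% and 27.5%, in other neuron-like nuclei 43.4%, 29.0% and 40.2% and in support cell-like nuclei 3.85%, 4.55% and 8.18%, so other neuron-like nuclei, with median depths of 8311, 5613.5 and 7416.5 UMIs, stood above the olfactory class in all libraries and unnamed nuclei did so in foragers. Named receptors were 36 genes, so a nucleus that used an unnamed receptor counted as having none.

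Receptor genes that neighbour each other in the genome were found in the same nuclei. Summed over all pairs with starts within 20 kb, shared nuclei came to 608 in newly emerged workers against 56.3 under independence, 108 against 5.42 in nurses and 265 against 15.8 in foragers, ratios of 10.8, 19.9 and 16.8. A nucleus counts for each pair it shares, and the sums came from 271, 62 and 104 different nuclei. Their mean Jaccard index was 0.0890, 0.0875 and 0.0900. Pairs on other chromosomes shared fewer nuclei than independence predicts, with ratios of 0.176 (0.0926 to 0.282 over resampled nuclei), 0.263 (0.0577 to 0.521) and 0.602 (0.313 to 0.937), and mean Jaccard indices of 0.00101, 0.000930 and 0.00268. The comparison covered 34, 25 and 31 genes. Pairs are not independent replicates, since most share a gene with another pair.

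The 6 neighbouring pairs with the highest mean Jaccard index all lay in a run of receptor genes on chromosome 2. Or56 and Or57, at 10134234 and 10139205, came first with a mean of 0.280, and shared 52, 16 and 21 nuclei in newly emerged workers, nurses and foragers against 4.03, 0.745 and 0.852 under independence. Or25 and Or26, at 10046322 and 10049035, followed with 0.254, then Or55 and Or56 with 0.244, Or25 and Or27 with 0.224, Or26 and Or27 with 0.220, and Or55 and Or57 with 0.192. The excess was smaller at longer distance. For starts up to 5 kb apart the ratio was 14.1, 27.1 and 23.4, and for 20 to 50 kb it was 3.29, 5.49 and 5.77. For 50 to 1000 kb on the same chromosome it was 0.777, 0.296 and 1.22. Pairs of Or151 with genes of the run lay farther apart and fell in no bin. Similar receptor genes can share reads, and how the authors' counting split such reads was not given in the sources used here, so counts of single receptors in this run are uncertain.

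**Figure D3:**
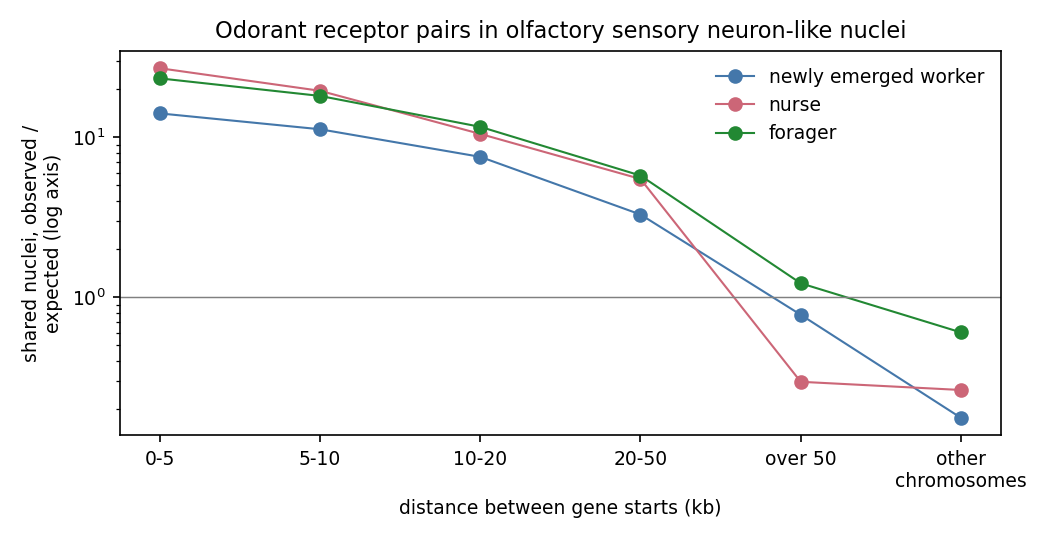
Nuclei shared by pairs of odorant receptor genes, summed over pairs, as observed over expected under independence (log axis), against the distance between gene starts in kb, in olfactory sensory neuron-like nuclei of the 3 libraries, with points for distance bins and a grey line at 1. The ratio lay at 14.1, 27.1 and 23.4 for starts up to 5 kb apart and at 0.176, 0.263 and 0.602 for genes on other chromosomes, in newly emerged workers, nurses and foragers. The bin labelled over 50 covers 50 to 1000 kb.

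Peaks of open chromatin were rare at odorant receptor genes. A peak within 500 bp of the start was found for 2 of 36 receptors in newly emerged workers (Or30-b and Or115), 1 in nurses (Or35) and 0 in foragers, shares of 5.56% (0.680 to 18.7), 2.78% (0.0703 to 14.5) and 0% (up to 9.74). Protein-coding genes of matched expression had a peak in 58.7%, 61.3% and 54.0%, and 0 of 10000 matched lists had a share as low in any library. Or2 had a peak at its start in all 3 libraries. The run on chromosome 2 spans 160 kb from Or4 at 9982958 to Or58 at 10142917 and holds 25 named receptors, 26 unnamed protein-coding genes and 10 long non-coding RNAs. Of the receptors 22 lay on the plus strand and 3 had no strand set, and all 10 non-coding RNAs lay on the minus strand. Or4, the first gene of the run, had no peak within 500 bp in any library, with the nearest at 7927, 9421 and 7942 bp. Of the 24 later receptors 1, 1 and 0 had a peak, and the run held 5, 4 and 0 peaks. Peaks were called per library by the authors, so a receptor that is open in few nuclei can lack one.

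**Figure D4:**
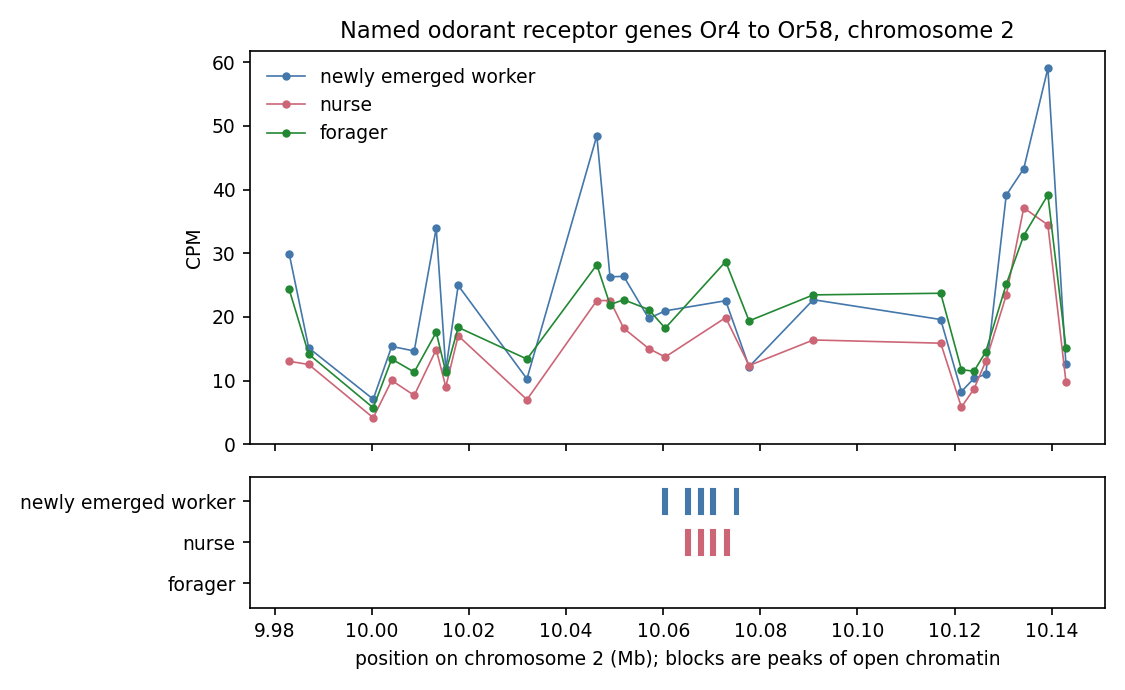
Expression of the 25 named odorant receptor genes of the chromosome 2 run in olfactory sensory neuron-like nuclei (CPM, upper panel, points at gene starts joined by lines) and the position of open chromatin peaks (lower panel, blocks) along chromosome 2 in Mb, for the 3 libraries. The run holds 5 peaks in newly emerged workers, 4 in nurses and 0 in foragers, and no error bars are drawn.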

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

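The removal of nuclei with high doublet scores, totals without mitochondrially encoded genes the addition of unnamed genes of the chromosome 2 run, repeated random draws of UMIs and the resampling of nuclei were chosen after results were seen, and the other settings before. No paired analysis was possible because each group had 1 library. Of 894 alternatives for 134 gene ratios, 708 stayed within the counting interval, 175 left it with the same direction or without a clear one before, and 11 turned the direction. Of 730 for 87 list medians, 587 stayed, 135 left and 8 turned. Of 135 for 21 shares, median absolute ratios and pair ratios, 86 stayed and 49 left, and of 27 for the 3 shares of nuclei with 2 or more receptors, 12 stayed and 15 left. The share of receptors with a peak at the start was the same at every distance and peak minimum. Where nothing else is said, the cause was not tested.

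The share of olfactory sensory neuron-like nuclei moved most when the class was taken from Or2 UMIs alone. Nuclei with 1 or more Or2 UMIs were 83.2% in newly emerged workers, 68.1% in nurses and 72.2% in foragers, so foragers then stood above nurses, and 56.6%, 50.5% and 47.7% after thinning, with foragers below nurses again. With a filter of 1000 UMIs and 500 genes the share was 74.3% in nurses and 57.4% in foragers, and with no filter 70.3% in nurses. At resolution 2 it was 58.4% in foragers. Keeping the 3 called doublets, all in the nurse library, gave 59.8% in foragers, so cluster borders alone moved this share.

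Equal class shares gave a median absolute log2 ratio of 0.53 for nurse over newly emerged worker and 0.47 for forager over newly emerged worker. They turned Or2 over all nuclei to 0.25 for nurse over newly emerged worker, 0.16 for forager over nurse and 0.41 for forager over newly emerged worker, and Mrjp9 and Cac for nurse over newly emerged worker to 0.79 and 0.18. For forager over newly emerged worker they turned the neuron markers to 0.13, odorant receptors to 0.30, detoxification genes to -0.22 and For to -0.59, and for forager over nurse the biogenic amine receptors to -0.0173 and hormone response genes to -0.0216. By construction these turns come from the weight given to each class, as a class of few nuclei counts as much as the largest. Or2 in the 52 support cell-like nuclei of newly emerged workers stood at 55.0 CPM from 12 UMIs, against 414 in nurses and 422 in foragers. In the olfactory class it stood at 1185, 1067 and 1147 CPM in newly emerged workers, nurses and foragers. DESeq2 size factors turned the odorant receptor median for forager over nurse to -0.00574, the hormone response median to -0.20, and Cac for nurse over newly emerged worker to 0.00213. TMM scaling turned the hormone response median to -0.18. Within the olfactory class TMM scaling turned Or2 to 0.0105 for nurse over newly emerged worker and -0.0709 for forager over nurse, and DESeq2 size factors to 0.0757 and -0.107.

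Receptors per nucleus followed depth and the UMI minimum. The share with 1 or more receptors, in newly emerged workers, nurses and foragers, was 33.5%, 16.3% and 22.1% without thinning, 4.18%, 2.29% and 2.53% at 500 UMIs, and 20.2%, 14.2% and 15.2% at 2000 UMIs. It was 34.6%, 27.8% and 34.9% at a minimum of 1 UMI, so newly emerged workers and foragers then stood level, and 3.75%, 1.59% and 1.91% at 3 UMIs. With the unnamed genes of the run it was 13.3%, 8.31% and 8.84%. Without the nuclei of high doublet score it was 6.23% in nurses and 6.21% in foragers, and with doublets kept 6.20% and 5.74%, but these values come from other random draws as well. Over 100 draws the means were 5.63% and 6.38% without those nuclei and 5.40% and 6.06% with doublets kept.

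Observed over expected shared nuclei of neighbouring receptors stayed above 5 at every setting. Within 10 kb it was 12.9 in newly emerged workers and 21.0 in foragers, and within 50 kb 6.79, 13.6 and 11.2 in newly emerged workers, nurses and foragers. In the same order it was 5.73, 7.31 and 5.67 at a minimum of 1 UMI, 16.7, 50.6 and 37.3 at 3 UMIs, and 9.72, 13.8 and 14.2 with the unnamed genes of the run. For other chromosomes it was 0.579 in newly emerged workers and 0.610 in nurses at 1 UMI, and 0 in nurses at 3 UMIs, from 8 pairs. Depth limits the count of receptors, as a median nurse nucleus held 2242 UMIs, and a receptor missed at this depth is not shown to be absent.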

Other observations

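Every test in this part was chosen after the results it bears on had been seen, and so were Or151, the profile along the receptor run and the clusters picked out. Or151 was higher outside the olfactory class than in it, at 169, 137 and 128 CPM outside in newly emerged workers, nurses and foragers. Or130 stood at 25.1 CPM outside against 10.4 in the class in newly emerged workers. It was near level in nurses, at 13.8 against 13.7, and in foragers, at 18.2 against 17.3. Or130 was also among the leading genes of olfactory sensory neuron-like clusters 8 and 16. Other receptors were not compared in cluster 20. In cluster 20, an unnamed cluster present in all libraries, a UMI of Or151 was found in 33 of 37 nuclei of newly emerged workers, 24 of 27 of nurses and 20 of 20 of foragers. In the olfactory sensory neuron-like class it was found in 2.80%, 1.14% and 4.46% of nuclei, and in all other nuclei in 8.89%, 8.57% and 17.3%. Its level in cluster 20 was 1212, 2249 and 1943 CPM, against 36.3, 9.87 and 28.6 CPM in the olfactory class, while Or2 in cluster 20 was 147, 194 and 330 CPM. Median depth in cluster 20 was 6483, 3571 and 4846.5 UMIs. Cluster 20 had 4 support markers raised, with Obp2 at 22493 CPM, and 0 neuron markers above the midpoint, but no support marker stood among its leading genes, so the naming rule left it unnamed.

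In the chromosome 2 run, genes downstream of the gene with the most UMIs held more RNA on average than genes upstream of it. The profile covered 51 protein-coding genes, 25 named receptors and 26 genes without a name. Downstream here means at a higher position on the chromosome, the direction of the 22 receptors set on the plus strand. Strand was not set for 3 receptors and was not checked for the 26 genes without a name. In nuclei where the highest of them had 3 or more UMIs, 573 in newly emerged workers, 162 in nurses and 225 in foragers, the next gene downstream held a mean of 1.27, 1.03 and 1.09 UMIs and the next gene upstream 0.485, 0.503 and 0.667. The ratios were 2.61 (2.26 to 3.03), 2.05 (1.55 to 2.72) and 1.63 (1.32 to 2.02). For genes 3 to 8 places away they were 4.26 (3.79 to 4.80), 3.41 (2.62 to 4.47) and 3.17 (2.62 to 3.86). Among adjacent pairs, the downstream gene was the higher of the 2 means in 30 of 30 pairs in newly emerged workers, 6 of 10 in nurses and 11 of 15 in foragers.

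The first pattern weighed was the sharing of nuclei by neighbouring receptor genes. Multiplets or free RNA would also join receptors of different chromosomes, yet the highest observed over expected value for those pairs was 0.602, below 1 by its interval over resampled nuclei (0.313 to 0.937), which excludes this as the whole cause. RNA that runs past a gene end and stops within the next gene would leave genes 3 to 8 places away even on both sides. The lowest downstream over upstream ratio there was 3.17. That ratio was not adjusted for the level of each gene, and its sides were set by position and not by strand. Its interval takes UMIs of 1 nucleus as independent. The ratio therefore does not exclude this cause, and RNA that runs past several gene ends stays open too. Reads shared between similar copies stay open, as no sequences were used and the next-gene ratio of 1.63 or more does not decide it. RNA past several gene ends, or a transcript made to run through several receptors, would give the same direction, and this was not tested on reads.

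The next pattern was the lower level of RNA for energy metabolism and ribosomal proteins in nurses than in newly emerged workers, taken in the olfactory class with mitochondrially encoded genes left out of the totals. For oxidative phosphorylation genes depth is excluded as the whole cause, since 248 newly emerged worker nuclei no deeper than the nurse median still stood at 1.98 (1.58 to 2.45) over nurses, and ribosomal protein genes stood at 0.89 (0.48 to 1.10) there, against 1.04 in all nuclei. Carried-over cytoplasm cannot be told apart from a change in the cells. The 941 newly emerged worker nuclei with the lowest mitochondrial share stood at 1.99 (1.69 to 2.31) for oxidative phosphorylation genes and at 0.41 (0.25 to 0.61) for ribosomal protein genes, against 3.15 and 1.53 in the 941 with the highest, but their median mitochondrial share of 0.605% was still above the 0.0564% of nurses. Age and library preparation were the same contrast, so a biological cause stays open and untested.

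The last pattern was Or2 RNA outside the neuron classes. Free RNA alone would reach all clusters of a library to a like degree, but in foragers Or2 in cluster 10 stood at 54.3% of the olfactory level and in cluster 11 at 5.96%, a ratio of 9.11, which excludes an even background as the whole cause. Whole multiplets do not explain cluster 10, where median UMIs were at most 0.711 of those of the olfactory class, but in cluster 5 they were up to 3.40 times as high, which multiplets need. Neuron markers stood at 55.5%, 6.07% and 55.0% of the olfactory level in forager clusters 10, 11 and 5, close to Or2 in the first 2, so RNA of olfactory neurons carried into some clusters stays open. In forager nuclei outside the olfactory class, shared nuclei summed over pairs of receptors on different chromosomes came to 325 against 73.0 under independence, from 70 different nuclei, a ratio of 4.45 (2.61 to 6.53), so receptor counts there were not read as co-expression.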
